A study of Mus musculus with 9 samples.

How the data were processed

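RNA of day 10 dendritic cells (DCs) from 3 mouse groups was hybridised to Affymetrix arrays, and 9 arrays were analysed. The groups are wild-type B6, mice labelled CIITA-/-, for CIITA, the master transcriptional activator of the MHC class II genes, and mice labelled IAb-/-, for the class II beta chain gene H2-Ab1. Each group has 3 arrays, and the titles number them as experiments 1 to 3. Experiment 1 was run on one array design of 12654 probe sets and experiments 2 and 3 on another of 12488, so each group has 1 array in the smaller table of 3 arrays and 2 arrays in the larger table of 6. In 1 case, a CIITA-/- array, the title holds no experiment number; it was given 2, the only number left in its group. No label says whether arrays of a group came from separate mice or cultures, so p-values measure only the spread between these arrays, which may be technical.

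The deposited values are intensity values on a linear scale, 1 per probe set and array. The algorithm that made them is not given in the sources used here. As the values themselves show, the deposited arrays share one trimmed mean: the 2% trimmed mean lies between 2502.2 and 2502.6 in the 6-array table and at 2500 in the other. This does not match the bright end: the spike-in controls Cre and BioB read 99616 and 8534 on IAb-/- replicate 2 but 58224 and 4970 on IAb-/- replicate 3, and actin 210788 and 137677. On the other 4 arrays of that table Cre lies between 71464 and 79408. Between 21% and 26.4% of the values of an array lie below 0, which is how background-subtracted intensities behave for transcripts near or under the background. No array repeats another: Spearman correlations across probe sets lie between 0.946 and 0.971 in the 6-array table and between 0.931 and 0.933 in the 3-array table. The Gapdh 3' to 5' signal ratio lies between 0.84 and 0.877 in the first and between 0.785 and 0.807 in the second, so no array stands apart by that ratio. The number of arrays limits the precision of every value.

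Tests were run within the 6-array table. The deposited scale was kept, since trimmed means agree within 0.015%. Values under the 30th percentile of the table (123.5) were set to it, log2 was taken, and probe sets above it on at least 2 arrays were tested, which left 9312 of 12422 probe sets that are not controls and 6718 genes. One model (lmFit and eBayes of limma 3.58.1 in R 4.3.3) was fitted to all 3 groups, which share one estimate of the spread with 3 residual degrees of freedom. A probe set counts as called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on this floored scale, which understates the change of dim probe sets. Experiment 1 took no part in the fit, and its within-experiment log2 differences, floored at 93.2, are given as an outside check.

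Because the deposited values have no detection call, a noise limit was set after the data were examined: the 95th percentile of the sizes of the negative values, 1701 in the 6-array table and 2203 in the other. Below it on every array lie 46.8% of the probe sets of the larger table. A probe set below it on every array of both groups compared is described as within noise. Where only one group lies below it, the fold is given as a bound, "at least N-fold", the bright group against the limit, unless that is under 1; a log2 value beside a bound is on the floored scale and gives no size.

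Gene symbols come from the platform's annotation table. Of the 12488 probe sets, 10833 have 1 symbol, 396 several, 1193 none and 66 are controls; of the 12654, the numbers are 10276, 363, 1949 and 66. Probe sets with several symbols were left unnamed. Both tables share 9977 probe set names, and the 8724 with 1 symbol in both have the same symbol. Genomic positions of the probes were not used here.

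Before the data were examined, 23 gene lists were fixed: class II presentation; plexins, semaphorins and neuropilins; MHC class I presentation; DC maturation; interferon-induced genes; inflammatory cytokines and chemokines; lysosomal proteases; DC lineage; cholesterol synthesis; glycolysis and hypoxia; proliferation; immediate early and heat shock genes; ribosomal proteins; genomic neighbours of Ciita and of H2-Ab1; and markers of macrophages, neutrophils, T, B, NK, mast, erythroid and fibroblast cells. Each was tested with camera (preset correlation 0.01) on the brightest probe set per gene, with adjustment over the 69 tests of 23 lists in 3 comparisons. The same test with an estimated correlation, and fry, were run beside it. With an estimated correlation no list passed in any comparison, and the lowest adjusted p was 0.6. A call lost there therefore does not single out a list. Fry p-values are unadjusted and are given for the class II list.

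The rule for the genes named was also fixed before the data were examined. It takes Ciita, H2-Ab1 and Plxna1, every class II member, the 10 genes per direction with the largest change among those called, filled up by smallest p where fewer passed, and up to 4 members with the largest change of each other list described. Probe sets without exactly 1 symbol could be left out, and the text leaves out part of the dim genes of this rule. Any other gene is said to have been chosen after its values were seen.

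The experiment number may stand for pairing, because the titles call it an experiment. It was used as a block only in alternatives, and the main tests ignore it. The correlation of same-numbered arrays' deviations from their group means is 0.05 for B6 with CIITA-/-, 0.08 for B6 with IAb-/- and 0.21 for CIITA-/- with IAb-/-. The main model, fixed without the block, has 3 residual degrees of freedom, and the blocked one has 2.

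Alternatives tried were other scalings (quantile, cyclic loess), floors, filters, an asinh scale, another variance model, only the 2 groups compared, the replicate block on 6 and on all 9 arrays, a fold threshold, and leaving out each array. The test was run on simulated data with known answers for CIITA-/- against B6. Of changed probe sets it called 33.2% at 2-fold, 81.2% at 4-fold, 88% at 8-fold and 95.6% at 16-fold. Changed probe sets were drawn only from those with a mean above the median, 200 in each of 5 runs. These rates do not cover dim probe sets. Where fewer probe sets change, the adjustment is stricter and the rates may be lower. An uncalled gene is therefore not shown to be unchanged. Of the 900 calls in the simulated data, 155 (17.2%) were false, above the 5% aimed at. Of these false calls 136 were within noise in both groups. A called probe set within noise is therefore weak evidence. The list test found 100 of 100 simulated lists lowered by 1 on the log2 scale, and 1 of 100 unchanged lists. These lists held 10 of the brighter genes each, and every gene was simulated independently. The result therefore does not cover lists whose genes vary together, or smaller shifts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.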

Results

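Transcript levels were measured on 9 Affymetrix arrays of day 10 dendritic cells, the antigen-presenting cells that show peptides to T cells on MHC class II molecules. There were 3 arrays each of B6 cells, of cells labelled CIITA-/- and of cells labelled IAb-/-. Fold changes and tests come from the 6 arrays of experiments 2 and 3 (n = 2 per group), and levels are in arbitrary intensity units given as mean ± SD. The 3 arrays of experiment 1, on another array design, are given beside them as an outside check of direction.

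The genes targeted per the labels were read first. The Ciita probe set gave 623 and 933 on the B6 arrays of experiments 2 and 3, 1601 and 1639 on the arrays labelled CIITA-/-, and 398 and 644 on those labelled IAb-/-. All 6 values lie under the noise limit of 1701, and the difference between CIITA-/- and B6 (log2 1.09, SE 0.32) did not pass (limma, adjusted p = 0.77). The H2-Ab1 probe set gave 17261 and 21348 on B6 arrays and still 16070 and 9621 on the arrays labelled IAb-/-. In experiment 1 it gave 44048 and 30749. Where either probe set lies relative to the deleted part of its gene is not known here, so neither checks its label, and directions drawn from these groups rest on the labels.

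The first comparison asks which transcripts differ between dendritic cells labelled CIITA-/- and B6. In the arrays labelled CIITA-/-, genes of the class II molecule fell steeply. H2-Aa, the alpha chain of I-A, went from 52492 ± 1535 in B6 to -1887 ± 519, at least 30.9-fold lower (log2 fold change -8.73, SE 0.26, limma adjusted p = 0.0081). H2-Eb1, the beta chain of I-E, went from 28240 ± 3079 to 937 ± 173, at least 16.6-fold lower (adjusted p = 0.036). H2-DMb2, a chain of the H2-DM molecule that loads peptides, went from 4388 ± 217 to 302 ± 2, at least 2.58-fold lower (adjusted p = 0.036).

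Other class II members were lower by value without passing over all probe sets. H2-Ab1 was at 363 ± 356 against 19304 ± 2890 in B6, at least 11.3-fold lower (log2 -6.12 on the floored scale, SE 0.81, adjusted p = 0.28). H2-DMb1 was at 4085 ± 2010 against 14895 ± 616 (log2 -1.96, adjusted p = 0.6). H2-DMa, the partner chain of H2-DM, had a log2 difference of -0.86 (adjusted p = 0.88). Cd74, the invariant chain that escorts class II through the cell, was not lower, at 144281 ± 3132 against 133951 ± 6162 (log2 0.11, SE 0.24). The chains of H2-DO, an inhibitor of H2-DM, had log2 differences of 0.23 (H2-Oa) and 0.31 (H2-Ob, within noise), with limma adjusted p = 0.95 and 0.93.

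As a group, 6 of the 10 measured class II members passed as lower when adjusted over the list alone. Over all probe sets 3 passed as lower, and none passed as higher. The 6 are H2-Aa, H2-Ab1, H2-Eb1, H2-DMb1, H2-DMb2 and H2-Ea. H2-Ea was within noise on every array, at 75 ± 50 against 190 ± 41 in B6 (limma, adjusted p = 0.049 over the list alone). In experiment 1 it read -178 against -99 in B6, a floored difference of 0. Its call is therefore not evidence of a fall. The list was lower against all other genes (camera, adjusted p = 2.31e-08), but not past the threshold with an estimated correlation (adjusted p = 0.6, unadjusted 0.054). No list passed that version in any comparison, so this is not particular to class II. By fry the class II list had an unadjusted p of 0.0024. In experiment 1 the log2 differences were -8.5 for H2-Aa, -6.03 for H2-Ab1, -4.94 for H2-Eb1, -3.68 for H2-DMb2 and -1.72 for H2-DMb1. H2-Oa (-0.69) and H2-Ob (-1.69) went the other way there, and Cd74 was higher (1.25).

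**Figure D1:**
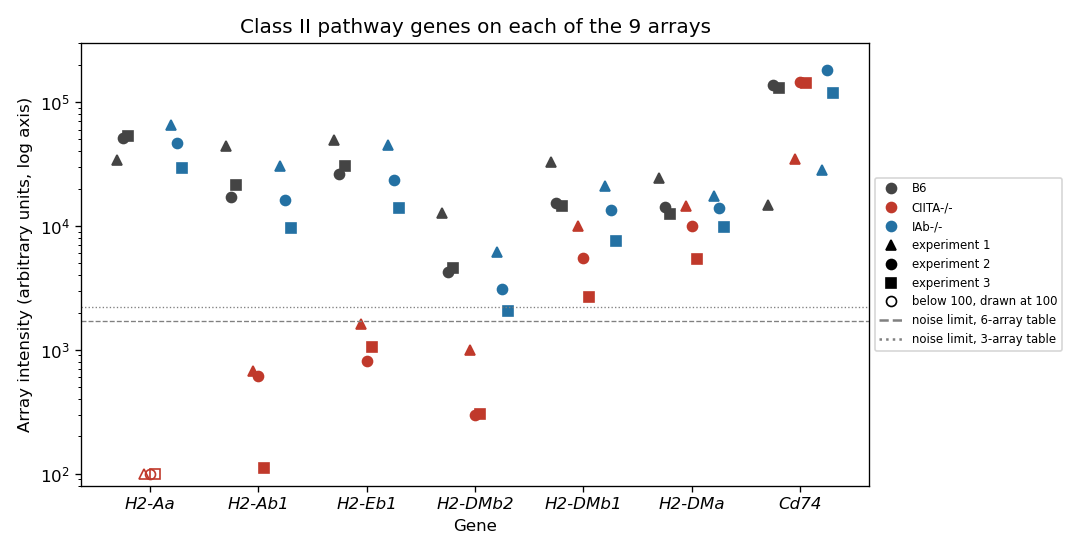
Intensity of 7 class II pathway genes on each of the 9 arrays (log axis, arbitrary units; H2-DMa by its brighter probe set), with colour for the group and shape for the experiment; open symbols lie below 100 and are drawn there, and the lines mark the noise limits of 1701 and 2203. H2-Aa, H2-Ab1, H2-Eb1 and H2-DMb2 lie under the noise limit on the arrays labelled CIITA-/- and mostly far above it elsewhere, while Cd74 does not follow them; levels across the array designs are not comparable.

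Over all genes, 9 of 9312 probe sets passed in this comparison, 2 higher and 7 lower. In 7 of these 9, H2-Aa among them, a whole group lay at the floor, against 522 of the 9312 tested. The floor sets the spread of such a group to 0, so the SE and p-value count none of it. An unadjusted p under 0.05 (limma) was reached by 546, where that threshold alone gives 466. Unchanged groups simulated with the same spread per probe set gave a mean of 505.4 (439 to 570 over 100 simulations). The 546 lie within that range. Each probe set was simulated independently, so the range may be too narrow for arrays whose probe sets vary together. Beyond class II, Emid1, which encodes an extracellular matrix protein, fell from 1781 ± 110 to -745 ± 140 (at least 1.05-fold, limma adjusted p = 0.032). Its CIITA-/- arrays lay at the floor, and the gene's other probe set had the opposite sign. The other 5 calls were within noise in both groups: Kcnk7 (log2 3.03) and Bmp10 (2.88) were higher, and Zfp1 (-3.37), Chrm4 (-2.30) and Il13 (-2.28) lower. Of the 6 calls with a difference in experiment 1, 4 had the same sign there. Leaving out either B6 or either CIITA-/- array, which leaves a group of 1 and fewer degrees of freedom, left 0 calls, and leaving out an IAb-/- array left 1, H2-Aa. On the floored scale log2 values ran from -8.76 to -8.70 for H2-Aa, from -5.11 to -4.73 for H2-Eb1 and from -3.91 to -3.81 for H2-DMb2. Both CIITA-/- values of H2-Aa lie under the floor, so leaving out either could not move its log2 value. Those of H2-Eb1 and H2-DMb2 lie under the noise limit, so these narrow ranges do not fix the size of the folds. With the experiment as a block no probe set passed (limma, 606 at an unadjusted p under 0.05), and H2-Aa had an adjusted p of 0.093. With the block over all 9 arrays, 4 of 8145 passed, all class II genes: H2-Aa (adjusted p = 0.006), H2-Eb1 and H2-DMb2 (both 0.0079) and H2-Ab1 (0.045).

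Plexin-A1, known from background as a target of CIITA in dendritic cells, could not be measured well. Its Plxna1 probe set gave 1102 and 991 on B6 arrays, -1931 and 1086 on those labelled CIITA-/-, and 667 and -900 on those labelled IAb-/-, all within noise (CIITA-/- against B6 log2 -1.51, SE 1.3, adjusted p = 0.93). In experiment 1 it gave 1810, -805 and 2398. None of the 14 measured plexins, semaphorins and neuropilins passed, and the list did not differ (camera, adjusted p = 0.393). Among its brighter members, Sema7a had a log2 difference of -0.42 (adjusted p = 0.93).

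A further 3 lists passed in CIITA-/- against B6 with small shifts. The DC maturation list, which holds costimulatory and activation genes, was lower (adjusted p = 0.00414; 0.6 with an estimated correlation), with 0 of 21 members passing. Il15, a cytokine that sustains lymphocytes, had a log2 difference of -1.09 within noise, Tnfrsf9 one of -0.42 and Cd200 one of -0.40. In experiment 1 the list's median was 0.1, the other way, and the call was lost without CIITA-/- replicate 3 (adjusted p = 0.09) and with the block over all 9 arrays (0.41). The cholesterol synthesis list was lower (adjusted p = 0.0402; 0.6 with an estimated correlation), with 0 of 16 members passing and 8 within noise. Its values included Msmo1 at log2 -1.02 and Dhcr7, which makes cholesterol in the last step of one branch of the pathway, at -0.66, both within noise. The median was -0.31 over all 16 members and -0.05 over the 8 above noise. In experiment 1 it was -0.21, the same direction. Its call was lost without CIITA-/- replicate 2 (adjusted p = 0.32), CIITA-/- replicate 3 (0.086) or B6 replicate 3 (0.32), and with the block over all 9 arrays (0.23). The fibroblast list was higher (adjusted p = 0.0134; 0.6 with an estimated correlation), but 10 of its 13 members were within noise, its experiment 1 median was -0.08, and the call was lost without B6 replicate 2 (adjusted p = 0.075) or CIITA-/- replicate 2 (0.2) and with the block over all 9 arrays (0.63). Fbln2 (267 ± 39 against -11 ± 50, within noise) passed when adjusted over the list alone.

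The next comparison sets the arrays labelled IAb-/-, where the label names the class II beta chain gene rather than its activator, against B6. In the arrays labelled IAb-/-, no class II gene passed against B6. H2-Aa was at 38124 ± 12520 against 52492 ± 1535 (log2 -0.50), but at 65738 against 33825 in experiment 1, the other way. H2-Ab1 was at 12846 ± 4560 against 19304 ± 2890 (log2 -0.63, SE 0.81; -0.52 in experiment 1) and H2-Eb1 at 18701 ± 6816 against 28240 ± 3079 (log2 -0.64; -0.15). H2-DMb2 was at 2576 ± 759 against 4388 ± 217 (log2 -0.80, SE 0.24, adjusted p = 0.99; -1.06 in experiment 1). Log2 differences of the others were -0.56 for H2-DMb1, -0.19 for H2-DMa, 0.14 for Cd74, 0.63 for H2-Oa, -0.01 for H2-Ob and -0.60 for H2-Ea, the last pair within noise. The IAb-/- arrays differed at the bright end: the Cre spike read 99616 in replicate 2 and 58224 in replicate 3, against 71464 to 79408 on the other 4 arrays, and actin 210788 and 137677. By fry the class II list had an unadjusted p of 0.32. By camera it was lower (adjusted p = 0.0469, and 0.72 with an estimated correlation), with 0 of 10 members passing over the list alone. That call was lost without IAb-/- replicate 3, where H2-Ab1 was at 9621 against 16070 in replicate 2 (adjusted p = 0.63), as without B6 replicate 3 (0.28), CIITA-/- replicate 2 (0.075) or CIITA-/- replicate 3 (0.057), and with the block over all 9 arrays (0.09).

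The clearest group shift in the arrays labelled IAb-/- was in inflammatory cytokines and chemokines, which were higher as a list (camera, adjusted p = 6.66e-05; 0.6 with an estimated correlation). Of 24 measured members 19 had a higher value, and 0 passed over the list alone. The next genes lay under the noise limit in B6, so their difference has only a bound. Ccl2, which attracts monocytes, was at 2019 ± 434 against 850 ± 576, at least 1.17-fold higher (adjusted p = 1). Il1a, an alarm cytokine, was at 2197 ± 26 against 1116 ± 296, at least 1.29-fold (adjusted p = 0.75), and Tnfaip2, induced by TNF, at 2279 ± 103 against 1169 ± 19, at least 1.34-fold (adjusted p = 0.57). Of the 5 members with an unadjusted p under 0.05 (limma), 3 had the opposite sign in experiment 1: Ptx3 (log2 2.27, within noise, and -1.50 there), Ccl4 (0.91 and -0.39) and Ccl3 (0.63 and -0.53). Tnfaip2, also among the 5, has no value there, since its probe set is not on that array design. Ccl3 and Ccl4 were named after their values were seen. The list's median was 0.5 in experiment 2, whose IAb-/- array has the brighter spikes, 0.16 in experiment 3 and 0.13 in experiment 1. The call held with the block over all 9 arrays (adjusted p = 4.1e-05, but adjusted p = 0.34 there with an estimated correlation) and without any 1 array, with the highest adjusted p (0.042) without IAb-/- replicate 2.

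A pair of other lists was higher. The lysosomal list had an adjusted p of 0.0102 (0.6 with an estimated correlation), 20 of 26 members with a higher value and 0 passing. Ctsk, a collagen-degrading cathepsin, had a log2 difference of 1.54 within noise, and Ctsb was at 67444 ± 11315 against 50856 ± 3878. In experiment 1 this list's median was -0.06, the other way, and the call was lost without IAb-/- replicate 2 (adjusted p = 0.099) or B6 replicate 3 (0.18) and with the block over all 9 arrays (0.23). The proliferation list had an adjusted p of 0.0178 (0.6 with an estimated correlation), 18 of 25 members with a higher value, 0 passing and 17 within noise, and a median of 0.29 in experiment 1. Its values included Stmn1 at log2 1.09 and Rrm2 at 0.92, both within noise and of the opposite sign in experiment 1 (-0.05 and -0.96). The list's median was 0.09 over all members and 0.07 over those above noise. That call was lost without B6 replicate 2 (adjusted p = 0.081), CIITA-/- replicate 2 (0.057) or IAb-/- replicate 3 (0.066), and with the block over all 9 arrays (0.12). The cholesterol synthesis list had an adjusted p of 0.0567, against 0.0444 with the experiment as a block, 0.12 with the block over all 9 arrays and 0.6 with an estimated correlation. Idi1, an isoprenoid enzyme of that list, was at 1511 ± 331 against 2878 ± 765 (log2 -0.92; -0.91 in experiment 1; adjusted p = 1).

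Gene by gene, 1 of 9312 probe sets passed in IAb-/- against B6. It was Zfp1 (log2 -3.37, limma adjusted p = 0.038), within noise in both groups and opposite in experiment 1 (4.39). Its IAb-/- arrays lay at the floor. An unadjusted p under 0.05 was reached by 401, where that threshold alone gives 466. Unchanged groups simulated with the same spread per probe set gave a mean of 509.6 (447 to 564 over 100 simulations). The 401 lie below that range, which again holds only for probe sets that vary independently. No probe set passed when any 1 array was left out, or with the experiment as a block (limma, 491 at an unadjusted p under 0.05). Among the smallest p-values above noise were Pim1, a kinase induced by cytokines, at 6023 ± 442 against 1880 ± 149 (log2 1.68, SE 0.19, adjusted p = 0.34; 1.08 in experiment 1) and H2-M3, a class I molecule that presents formylated peptides, at 1470 ± 32 against 3422 ± 220, at least 2.01-fold lower (adjusted p = 0.34; log2 -0.68 in experiment 1). The other probe set of H2-M3 had the opposite sign.

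**Figure D2:**
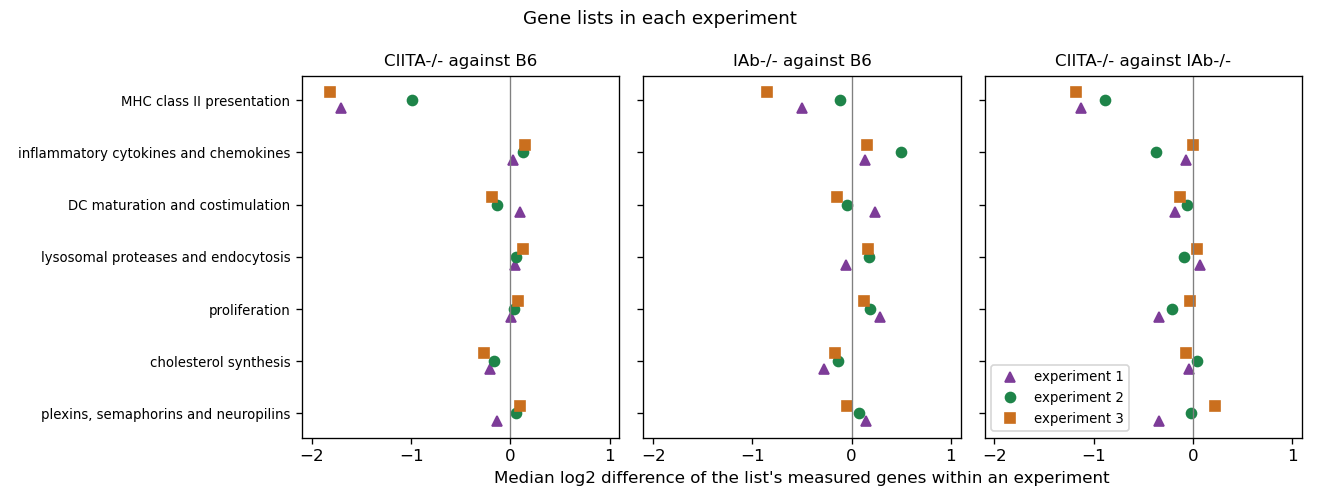
Median log2 difference over the measured genes of 7 lists, within each experiment, for the 3 comparisons (each point is 1 experiment, with 1 array per group; the line marks no difference). Class II genes lie between -0.99 and -1.82 for CIITA-/- against B6. Most other medians lie nearer 0. Some of these lists have all 3 experiments on the same side of 0, and others have experiments on both sides.

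The last comparison sets the groups labelled CIITA-/- and IAb-/- against each other. H2-Aa was at least 21.8-fold lower in the arrays labelled CIITA-/- than in those labelled IAb-/- (log2 -8.23, SE 0.26, limma adjusted p = 0.011; -9.46 in experiment 1). H2-Eb1 (at least 10.6-fold lower, adjusted p = 0.09), H2-Ab1 (at least 7.31-fold, adjusted p = 0.38) and H2-DMb2 (at least 1.48-fold, adjusted p = 0.091) passed only when adjusted over the list alone, which makes 4 of 10 members. Cd74 had a log2 difference of -0.03. The class II list was lower (camera, adjusted p = 2.31e-08, and 0.6 with an estimated correlation). By fry its unadjusted p was 0.0043.

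In this comparison inflammatory cytokines and chemokines were lower in CIITA-/- (adjusted p = 0.00783; 0.6 with an estimated correlation), with 0 of 24 members passing. The list's median was -0.37 in experiment 2, whose IAb-/- array has the brighter spikes, 0 in experiment 3 and -0.07 in experiment 1. The call held with the block over all 9 arrays (adjusted p = 0.021; adjusted p = 0.71 there with an estimated correlation) but not without CIITA-/- replicate 2 (adjusted p = 0.14) or IAb-/- replicate 2 (0.43). Cxcl1, which attracts neutrophils, was at 1059 ± 555 against 2135 ± 280, at least 1.25-fold lower (log2 -1.39 in experiment 1; adjusted p = 1). The mast cell list was lower too (adjusted p = 0.0435; 0.6 with an estimated correlation), but all 10 measured members were within noise. Of these Il13 (log2 -2.28; -3.67 in experiment 1) and Gata2 (-1.39; the other way in experiment 1, 2.75) passed over the list alone. The mast cell call was lost without IAb-/- replicate 2 (adjusted p = 0.4), CIITA-/- replicate 2 (0.08) or CIITA-/- replicate 3 (0.37), and with the block over all 9 arrays (0.52). In all, 2 of 9312 probe sets passed, H2-Aa and Kcnk7 (log2 3.03, within noise, and -1.84 in experiment 1), with 423 at an unadjusted p under 0.05 (limma). Each of the 2 had a whole group at the floor. Without either B6 array or either CIITA-/- array 0 passed, and without an IAb-/- array 1 did, H2-Aa. With the experiment as a block 0 passed (limma, 492 at an unadjusted p under 0.05), and with the block over all 9 arrays 3 did, H2-Aa, H2-Eb1 and H2-DMb2. Above noise without passing, Pla2g7, which breaks down platelet-activating factor, was at 18449 ± 2080 against 8161 ± 8 (log2 1.17, adjusted p = 0.32; 1.22 in experiment 1), and the homeobox gene Hoxa4 at 11208 ± 25 against 4790 ± 658 (log2 1.23, adjusted p = 0.32; 0.81 in experiment 1). On B6 arrays Pla2g7 was at 18230 ± 129 and this Hoxa4 probe set at 9889 ± 44. Both lie nearer the CIITA-/- level, so the arrays labelled IAb-/- were the lower ones. The other probe set of Hoxa4, within noise, had the opposite sign (-0.16).

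The other lists passed in none of the 3 comparisons. Their smallest adjusted p was 0.0675 for MHC class I, 0.538 for interferon-induced genes and 0.881 for DC lineage genes. Among markers of other cells it was 0.145 for neutrophils, 0.252 for macrophages, 0.252 for B cells, 0.595 for T cells, 0.277 for NK cells and 0.572 for erythroid cells. It was 0.415 for glycolysis and hypoxia, 0.818 for immediate early and heat shock genes, 0.252 for ribosomal proteins, and 0.252 for the neighbours of Ciita as for those of H2-Ab1.

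Changes against B6 in both labelled knockout groups were correlated across the 9312 probe sets (Pearson r = 0.526, Spearman rho = 0.517), but both use the same B6 arrays, and probe sets are not independent replicates. Unchanged groups simulated against shared controls gave r = 0.499 and rho = 0.444, and 66.6% of probe sets with the same sign against the observed 70.2%. The covariance, 0.122, equalled the simulated 0.122. With a different B6 array for each group r was 0.137 or 0.092. At an unadjusted p under 0.05, 76 probe sets were higher and 69 lower in both, against 6.83 and 4.993 for independent lists. Unchanged groups simulated against the shared controls gave means of 78.9 and 78.8 (57 to 99 and 60 to 106 over 100 simulations). The observed counts lie within these ranges, for which probe sets were simulated independently. The simulated lists, however, held on average 505.4 probe sets for CIITA-/- and 509.6 for IAb-/-, against 546 and 401 observed. List lengths were not matched, so whether the overlap exceeds what shared controls give is not decided.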

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

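The alternatives were fixed before the data were examined, except both floors at the noise limit and the block over all 9 arrays with an estimated correlation, which were chosen after. The first floor kept the tested probe sets, and the second, defined after seeing the first, tested only probe sets above that limit; both are given. A floor at the 10th percentile was not run, since the value there is -275.5 and has no log2. What limits depth here is signal over background: 46.8% of probe sets lie under the noise limit on every array.

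Counts of probe sets past the threshold are given in the order CIITA-/- against B6, IAb-/- against B6 and CIITA-/- against IAb-/-; the main counts are 9, 1 and 2. With no filter they were 14, 5 and 7, on the asinh scale 5, 0 and 5, and with a replicate block 0, 0 and 0. The block over all 9 arrays gave 4, 0 and 3. The noise-limit floor with the main filter gave 4, 5 and 4, sharing 0 with the main calls; with its own filter it gave 3, 0 and 4, sharing 2, 0 and 1, of which H2-Aa and H2-Eb1 for CIITA-/- against B6. A floor at the 50th percentile gave 5 for CIITA-/- against B6, and trend with robust eBayes 4 there and 0 for IAb-/- against B6. Only the 2 groups compared gave 1, 0 and 0, quantile normalization 3 for IAb-/- against B6, and a filter at the median 6 for CIITA-/- against IAb-/-. Without one replicate the counts ran from 0 to 1, from 0 to 0 and from 0 to 1, where a lone array is assumed to vary like the other groups; fewer arrays leave fewer degrees of freedom. The other causes were not tested.

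The class II list was lower in all 3 comparisons under every alternative run. For CIITA-/- against B6 and against IAb-/- it lost its call only with an estimated correlation (adjusted p 0.6 and 0.6). For IAb-/- against B6 it was also lost with that (0.72), with no filter (0.08), a filter at the median (0.13), the asinh scale (0.064), the replicate block over all 9 arrays (0.09) and the noise-limit floor with the main filter (0.081); without one replicate it ran from 0.00039 to 0.63. The plexin list passed nowhere. The ribosomal list, not called, was lower for IAb-/- against B6 without IAb-/- replicate 2 (0.014), and ran up to 0.99 without one replicate. Sign changes with no call on either side were 4 for the main lists, 101 for other lists and 70 for named genes. In 7 cases a within-noise call became exactly 0 under the noise-limit floor with the main filter. Named genes lost 136 calls over all alternatives and gained 28, other lists lost 51 and gained 30. The block on 6 arrays changed no list call but that of cholesterol synthesis.

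With a floor at the 50th percentile, called probe sets had the same sign in experiment 1 in 100% for each comparison (5 of 5, 1 of 1 and 3 of 3). The correlation of both labelled knockout groups' changes ran from 0.35 to 0.68 without one replicate, and was 0.14 or 0.09 with split controls.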

Other observations

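Among the tests below, those on the sign of dim calls in experiment 1, on swapped arrays and on cross-hybridisation were chosen after the result was seen, as were the values of the other 2 comparisons in the paragraph on experiment 1 and the spread within each experiment; the others had their limits set before. After the values were seen, a verdict was also made to need an interval clear of its limit and, for the array design, both kinds of correlation on one side. The genes of the next paragraph were chosen after their values were seen, and the estimated correlation over all 9 arrays was added after the list calls were seen.

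Neutrophil genes did not move together in the arrays labelled IAb-/-. Lcn2, an iron-binding antibacterial protein, was at 5650 ± 1308 against 1837 ± 189 in B6 (log2 1.61, adjusted p = 0.41 over all probe sets with limma, 0.012 over the list alone). Csf3r, the receptor for the granulocyte growth factor, was at 2342 ± 73 against 3816 ± 89 (log2 -0.70, adjusted p = 0.66 and 0.032), and was opposite in experiment 1 (1.62). Clec16a, a genomic neighbour of Ciita, was at 1550 ± 451 in CIITA-/- against 351 ± 83 in IAb-/- (log2 2.13 on the floored scale, with both means under the noise limit, adjusted p = 0.37 over all probe sets and 0.017 over the list alone; 1.54 in experiment 1). Cdk1, which drives entry into mitosis, was within noise (log2 -1.52 in CIITA-/- against IAb-/-, 2.44 in experiment 1). With the block over all 9 arrays, though not in the 6 arrays alone, 2 further lists passed, and neither did with an estimated correlation. Ribosomal protein genes were higher in CIITA-/- (camera, adjusted p = 0.0046; 0.88 with an estimated correlation) and in IAb-/- (adjusted p = 0.0059; 0.88) than in B6, where both comparisons share the B6 arrays. Their medians in experiments 1 to 3 were 0.17, 0.11 and 0.14 for CIITA-/- and 0.28, 0.23 and -0.09 for IAb-/-. Proliferation genes were lower in CIITA-/- than in IAb-/- (adjusted p = 0.0046; 0.34 with an estimated correlation; 0.0675 in the 6 arrays), with medians of -0.34, -0.21 and -0.03, and 16 of the 25 members of the 6-array table within noise.

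Of the called probe sets, 5 distinct ones were within noise in both groups compared. A floor that removes the spread of a dim group was tested on the asinh scale, which has no floor: 4 of the 5 kept an unadjusted p under 0.001 there. That equals the limit set in advance against the floor (80%), but its exact 95% interval runs from 28.4% to 99.5%, so the floor stays open. A genotype difference stays open too, since only 3 of the 5 had a difference in experiment 1 and 1 of those had the same sign. In simulated data 136 of 155 false calls were of this kind, so a false call may account for any of them.

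H2-Ab1 signal remained in the arrays labelled IAb-/-. A swap of B6 and IAb-/- arrays cannot alone account for the signal, because whichever of these 6 arrays are IAb-/- held signal too: the lowest lay 5.66-fold over its noise limit. Whether arrays were swapped is not settled by this, since the probe set may read a part of the gene that is not deleted. Cross-hybridisation of other class II transcripts cannot be told apart from a real transcript: the H2-Ab1 difference minus that of H2-Eb1 averaged -0.11 on the log2 scale, with -0.37, 0.04 and -0.02 in experiments 1 to 3. A transcript that the targeted allele still makes, or arrays of cells that were not knockouts, were not tested and stay open.

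For CIITA-/- minus B6, 4060 probe sets outside class II were compared. They were on both array designs and above the noise limit on at least 1 array of these groups in the 6-array table. The same sign was found for 49.5% in experiments 1 and 2, 49.8% in experiments 1 and 3, and 60.1% in experiments 2 and 3. Signal near the noise level was tested as the whole cause on the 1899 probe sets in the brightest 25% of those shared. Of these, 51.6% had the same sign in experiment 1 as in the mean of experiments 2 and 3. The 95% interval, 49.3% to 53.8%, lies under the 55% set in advance, but it counts probe sets of the same arrays as independent. The disagreement was thus not confined to dim probe sets. Its cause is not decided, because groups without real differences outside class II would give such a share at any brightness. The different array design stays open, because by Pearson experiments 2 and 3 correlated no better with each other than with experiment 1 (0.056, an excess of 0.02, under the limit of 0.1), and by Spearman they did (0.229, an excess of 0.23, over the limit of 0.2). In the other 2 comparisons the same-sign share of experiments 2 and 3 lay between those of experiment 1 with each: 52.5% against 56.1% with experiment 2 and 45.9% with experiment 3 for IAb-/- against B6 (excess -0.02 by Pearson, 0.04 by Spearman), and 47.7% against 56% and 46.1% for CIITA-/- against IAb-/- (excess 0 and -0.07). Among probe sets above noise with an unadjusted p under 0.05, class II included, 51.8%, 60.2% and 64.3% had the same sign in experiment 1 for CIITA-/- against B6, IAb-/- against B6 and CIITA-/- against IAb-/- (95% intervals 42.1% to 61.4%, 50.3% to 69.5% and 54% to 73.7%).

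Over all 9 arrays with the block, and only the 2 groups compared in the fit, 2 probe sets passed for CIITA-/- against B6, 0 for IAb-/- against B6 and 0 for CIITA-/- against IAb-/- (limma, 325, 314 and 265 at an unadjusted p under 0.05). As many or more passed in 3, 10 and 10 of the 10 splits, the real one included, and the highest other counts were 218, 452 and 354, but with 10 splits no share under 0.05 can be reached. Among the 3 other splits that part all 3 pairs of an experiment, as the real one does, the highest count was 0 in each comparison. The other 6 splits rest on 1 array against 1 within the experiment they part: the 2 that part experiment 1 gave those highest counts and the other 4 gave 0. As a structure of the samples this shows only that differences were wider within experiment 1, with an SD of 0.95, 0.97 and 0.96 on the log2 scale in the 3 comparisons against 0.58 to 0.71 in experiments 2 and 3, and the cause was not tested.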
